A study of Mus musculus with 6 samples.

How the data were processed

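RNA was measured by bulk RNA-seq in 6 libraries of sorted lung mesenchymal cells from adult mice, 3 Yeti+/- and 3 wild-type, grouped by the sample titles. Per the labels' protocols, RNA was isolated with a column kit, its quality was measured on an Agilent Pico chip, and sequencing was done by a service provider. The labels speak of cultured cells in the extraction protocol and of cells sorted from lung in the series design, and of tamoxifen injection without saying which allele it acts on, so neither point is settled here. FastQC, STAR and DESeq are named without versions per the submitters' processing notes, as are the builds GRCm38 and mm10, 2 names for the same mouse assembly. The read counter, its strand setting and the annotation release are not given in the sources used here.

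The values used are a single table of the authors' own comparison, with no values per library. Its mean expression column is a signal, the count per gene divided by a size factor and averaged over all libraries, per the file headers and from the values. The log2 fold change, its standard error (also log2) and the Wald statistic, a score equal to the fold change over its standard error within 4.25e-07, are the authors' DESeq2 values per the file headers. The p-value and adjusted p-value columns are the authors' deposited values as well, and a Benjamini-Hochberg adjustment recomputed over the same genes differed from the deposited one by at most 3.91e-06. The direction, Yeti over wild-type, is that of the table's name. Of 29322 genes, 29308 had a p-value and 20212 an adjusted p, the smallest mean count with an adjusted p being 4.57 in the authors' deposited table. A further 14 genes had no p-value, which DESeq2, the authors' tool, leaves out by default where a single library is an outlier in its group.

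The design fixed before the data were examined assumed counts and an edgeR test. edgeR was not used, since the table holds no counts; the fallback written in that design applied, namely the authors' fold changes and adjusted p-values as theirs and limma cameraPR on their statistic. Gene symbols and coordinates were taken from GENCODE M21 on GRCm38 by Ensembl identifier, which matched 29185 of the 29322 genes, and 24 symbols stored as dates were thereby restored. For genes sharing a symbol, the most abundant entry was used, which left 20197 genes for the list tests.

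Group levels were derived from the mean count and the fold change, assuming equal group sizes, and are printed as fitted levels. The size factors were recovered from the 21 distinct lowest means, which are the sums of pairs of 6 numbers within 2e-06. This explained all 1406 genes with a mean under 0.36 as 2 reads and all 939 genes with a mean between 0.45 and 0.54 as 3 reads. The factors were 1.09, 1.05 and 0.952 for wild-type and 1.00, 0.996 and 0.946 for Yeti, with the replicate each belongs to unknown, so libraries differed little in depth. The mean normalized counts summed to 26646632, and the 10 most abundant genes held 6.98% of them. A between-library coefficient of variation was derived for each gene from the standard error.

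The comparisons were tested with 31 gene lists and 22 genes fixed before the data were examined. Lists were tested two-sided with cameraPR of limma 3.58.1 (R 4.3.3), preset inter-gene correlation 0.01, with Benjamini-Hochberg adjustment over the 30 lists with at least 4 tested members; the sex-linked list had 1 gene with a row and was not tested. An estimated correlation needs values per library, so which list calls would hold with one cannot be stated. Named genes were the 12 highest and 12 lowest fold changes among genes with an adjusted p under 0.05, a mean above the median of the tested genes and a symbol that is not a predicted model, plus per list the 3 members with the smallest adjusted p and the most abundant member, and the fixed genes; other genes were chosen after their values were seen. Some genes that this rule names are not reported here. The further criterion that groups not overlap could not be applied. A further set of 12 lists and 8 tests, used only in the closing section, was written after the table had been looked through.

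The sex-linked list shows Xist at a mean of 21663 normalized counts and a log2 fold change of -0.20 ± 0.12 (SE) in the authors' deposited table, adjusted p = 0.750, and 0 of 4 Y-linked genes had a row.

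The calling step was tested on simulated data: fold changes for the 20197 genes were drawn around known values with each gene's own standard error, 20 times, with 200 genes changed. Of genes changed by a log2 fold change of 1, 54.6% were recovered, and of those changed by 2, 77.6%, and 5.00% of calls were false. Of 600 list tests with no list shifted, 1 was called, and a shifted list was called in 20 of 20 simulations. Errors were drawn independently for each gene, so these list rates do not cover lists whose members vary together between libraries. The share of false calls follows from the adjustment, since each error had exactly the stated standard error. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for all other steps.

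The alternatives were an adjusted p of 0.01, a fold minimum of 2 and adjustment over all genes with a p-value, and, chosen after seeing the data, a mean of at least 1 normalized CPM, an empirical null, recentred fold changes, Bonferroni adjustment, no immunoglobulin genes, a preset correlation of 0.05 and the rank version of cameraPR. Alternatives that need values per library (another count test or normalization, a replicate block, leaving out a library, an estimated correlation, other splits of the samples) could not be run.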

Results

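Bulk RNA-seq was done on lung mesenchymal cells of adult Yeti+/- and wild-type mice, 3 libraries per group. The Yeti allele is a gain-of-function allele of Ifng, the gene of interferon-gamma (IFN-γ), a cytokine made mainly by T and NK lymphocytes. Per the series design, cells were sorted by flow cytometry as negative for CD45, CD31 and Epcam, surface proteins of leukocytes, endothelium and epithelium, and for the dead-cell dye DAPI. The extraction protocol speaks of cultured cells and the labels of tamoxifen injection, and neither point is settled here. All values per gene come from the authors' deposited table of the Yeti against wild-type comparison, which gives 1 fold change with its standard error (SE) per gene and no values per library. The mean normalized counts in the authors' deposited table summed to 26646632, the average depth per library after the authors' scaling. The single comparison asks how the lung mesenchyme of mice with excess IFN-γ differs from that of wild-type mice.

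The Yeti libraries carried a broad interferon response, while most markers of fibroblasts, smooth muscle and pericytes did not pass the test. Bulk libraries do not show which of the cells in them carried the response. In the authors' deposited table, 574 of 20212 genes with an adjusted p passed 0.05 (DESeq2 Wald test, Benjamini-Hochberg), of which 373 were higher and 201 lower in Yeti. Of these, 240 rose and 174 fell by at least 2-fold in the authors' deposited table, and 55 rose and 28 fell by at least 8-fold. The genes that fell included immunoglobulin genes and endothelial markers, of cells that the sort was set to remove. Immunoglobulin genes made up 32.3% of the genes that fell in the authors' deposited table.

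**Figure D1:**
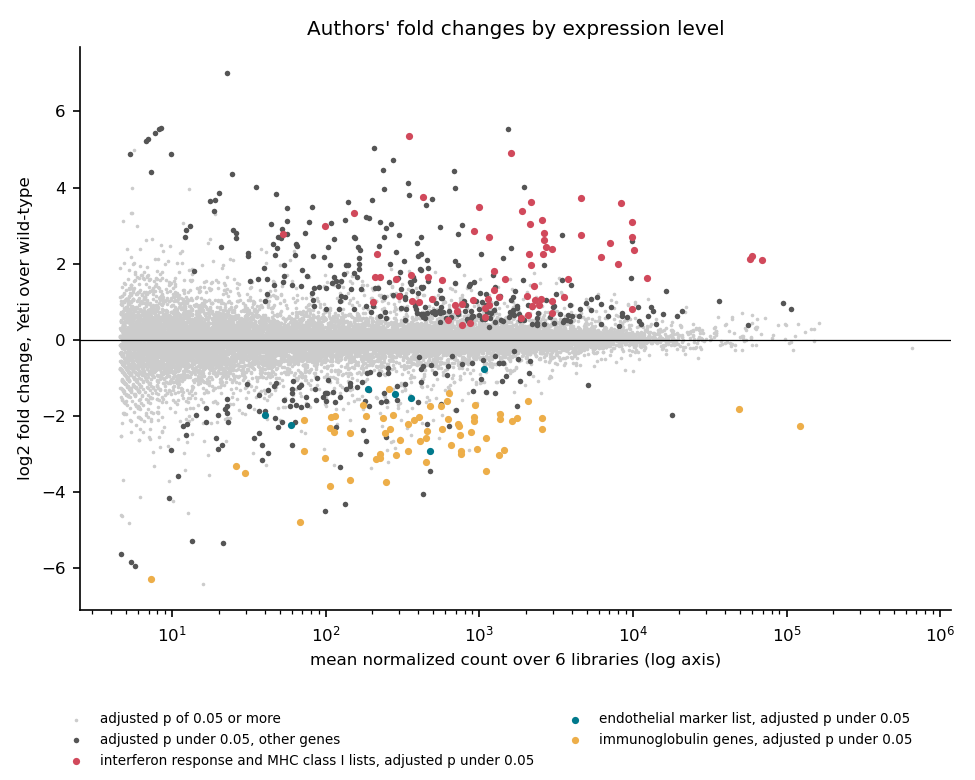
Log2 fold change of Yeti over wild-type (y axis) against the mean normalized count over the 6 libraries (x axis, log scale) for the 20212 genes with an adjusted p in the authors' deposited table, 1 point per gene. Coloured points are genes that passed 0.05 and belong to the interferon and MHC class I lists (all above 0), to the endothelial marker list (all below 0) or to the immunoglobulin genes (all below 0).

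The interferon-induced GTPases and their regulators rose together. Of the 41 tested genes of the IFN-γ response list, 36 rose and 0 fell in the authors' deposited table (38 adjusted over the list alone; 38 higher at an unadjusted p under 0.05), with a median log2 fold change of 2.25. Gbp10, a guanylate-binding protein of cell-autonomous defence (ENSMUSG00000105096, GRCm38 chromosome 5, 105215699 to 105239533), rose by 5.34 ± 0.38 (SE) on the log2 scale in the authors' deposited table, adjusted p = 1.35e-41. Tgtp2 (4.92 ± 0.25), Igtp (3.73 ± 0.24), Gbp4 (3.61 ± 0.29) and Ifi47 (3.38 ± 0.17), further members of the interferon-inducible GTPase families, rose in the authors' deposited table as well. The transcription factor gene Batf2 rose by 3.75 ± 0.23 in the authors' deposited table. The interferon-induced transcription factor gene Irf1 rose by 1.98 ± 0.27 and the feedback inhibitor Socs1 by 1.82 ± 0.24 on the log2 scale in the authors' deposited table. Socs3, the most abundant member (0.25 ± 0.22), and Cd274, which encodes the checkpoint ligand PD-L1 (0.72 ± 0.26, adjusted p = 0.153), did not pass in the authors' deposited table. Cd274 did pass adjusted over the list alone. Serpina3f, a serine protease inhibitor gene outside the lists (ENSMUSG00000066363, chromosome 12, 104214544 to 104221129), had the highest fold change of the genes named by rule in the authors' deposited table, 46.4-fold, adjusted p = 1.38e-54.

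Genes shared with the type I interferon response rose as well. Of 28 tested, 20 rose and 0 fell in the authors' deposited table (24 adjusted over the list alone), with a median of 1.10. The nucleic acid sensor Zbp1 rose by 2.69 ± 0.19, Ifi44 by 2.27 ± 0.23 and the ubiquitin-like Isg15 by 1.69 ± 0.18 in the authors' deposited table, and Ifi203, the most abundant member, rose by 1.01 ± 0.25. Ifit2 (-0.22 ± 0.29) and Ifi27l2a (-0.06 ± 0.18) did not pass in the authors' deposited table.

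The class I antigen presentation pathway rose as a whole, from heavy chains to immunoproteasome. Of 18 tested genes, 17 rose and 0 fell in the authors' deposited table (18 adjusted over the list alone), with a median of 1.62. H2-D1, the most abundant member, rose by 2.09 ± 0.16 to a fitted level of 112880 normalized counts in the authors' deposited table. H2-K1 rose by 2.21 ± 0.16 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347), H2-Q4 by 2.35 ± 0.13, the shared light chain B2m by 2.13 ± 0.16 and the peptide transporter subunit Tap1 by 2.17 ± 0.24 in the authors' deposited table. Class II genes did not pass one by one: 0 of 10 in the authors' deposited table, with 3 higher and 0 lower at an unadjusted p under 0.05, and 1, H2-DMb1, adjusted over the list alone. Cd74, the invariant chain and the most abundant class II member, stood at 0.85 ± 0.48 and H2-Ab1 at 1.07 ± 0.49 in the authors' deposited table. The class II list as a whole was higher (median 0.90, limma cameraPR on the authors' statistic, adjusted p = 0.0207), and the macrophage and monocyte list, whose cells are rich in class II transcripts, was also higher (median 0.60, adjusted p = 0.00668). With a preset correlation of 0.05 the class II list had an adjusted p of 0.0509.

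Several chemokines rose, Cxcl9, Cxcl10 and Ccl5 among them. In the authors' deposited table, 9 of 17 tested chemokines rose and 0 fell (14 adjusted over the list alone), with a median of 1.44. The macrophage and monocyte list was higher as well (median 0.60, adjusted p = 0.00668), and the median derived between-library coefficient of variation was 0.333 for 16 chemokines and 0.426 for the 19 macrophage and monocyte markers. Cxcl9, a ligand of the chemokine receptor Cxcr3 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), rose by 4.43 ± 1.01, and Cxcl10, a ligand of the same receptor, by 4.01 ± 0.38 to a fitted level of 3661 normalized counts in the authors' deposited table. Ccl19, which recruits Ccr7-bearing lymphocytes and dendritic cells, rose by 1.67 ± 0.40, Ccl5 by 1.58 ± 0.22 and Cx3cl1 by 1.38 ± 0.20 in the authors' deposited table. Cxcl14, the most abundant chemokine, was at 0.46 ± 0.19 and did not pass in the authors' deposited table. Of 12 cytokines and lymphocyte niche factors, 6 rose and 0 fell in the authors' deposited table (6 adjusted over the list alone), with a median of 0.57. Il18bp, the soluble antagonist of interleukin-18, rose by 1.87 ± 0.17, Il6 by 1.95 ± 0.56, Lif by 1.29 ± 0.31, Tslp by 1.13 ± 0.28 and the macrophage growth factor Csf1, the most abundant member, by 0.63 ± 0.19 in the authors' deposited table. The alarmin Il33 stood at 0.02 ± 0.37 in the authors' deposited table.

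Some complement and cell death genes rose. In the authors' deposited table, 4 of 12 complement genes rose and 0 fell (4 adjusted over the list alone): C4b by 0.96 ± 0.20, C2 by 1.02 ± 0.25, C1s1 by 0.75 ± 0.19 and C1ra by 0.69 ± 0.20. C3, the most abundant, stood at 0.45 ± 0.23 in the authors' deposited table. Of 16 cell death genes, 8 rose and 0 fell in the authors' deposited table (10 adjusted over the list alone), with a median of 0.68. Among them Mlkl, the executioner of necroptosis, rose by 1.46 ± 0.20, Apol9b by 1.97 ± 0.51 and the pyroptosis pore protein gene Gsdmd by 0.51 ± 0.14 in the authors' deposited table. On the authors' statistic, limma cameraPR called the IFN-γ (adjusted p = 8.16e-282), class I (1.70e-160), type I interferon (1.81e-54), chemokine (5.17e-25), cell death (4.05e-14), cytokine (5.68e-09) and complement (1.22e-04) lists higher.

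Ifng itself, whose allele defines the groups, was low in these sorted cells. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) had fitted levels of 14.9 normalized counts in wild-type and 24.4 in Yeti in the authors' deposited table. That is a log2 fold change of 0.71 ± 0.55 with an adjusted p of 0.919 in the authors' deposited table, and the derived between-library coefficient of variation was 0.41. The receptor chains Ifngr1 (-0.11 ± 0.16) and Ifngr2 (0.21 ± 0.14) and the receptor kinases Jak1 (-0.04 ± 0.13) and Jak2 (0.10 ± 0.21) did not pass either in the authors' deposited table.

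Few markers of the mesenchymal cell types passed. Of 19 adventitial fibroblast markers, 2 rose and 0 fell in the authors' deposited table (2 adjusted over the list alone): Ly6a (Sca-1) by 1.11 ± 0.20 and Ly6c1 by 0.97 ± 0.27. Pi16 stood at 0.06 ± 0.30 and Dcn, the most abundant, at -0.27 ± 0.31 in the authors' deposited table. Of 19 alveolar fibroblast markers, 1 rose and 0 fell in the authors' deposited table (1 adjusted over the list alone), the lipid droplet coat gene Plin2 at 0.60 ± 0.19, adjusted p = 0.0475. Pdgfra (-0.12 ± 0.17), Wnt2 (-0.16 ± 0.36), Fgf10 (-0.14 ± 0.13) and Inmt, the most abundant (-0.26 ± 0.28), did not pass in the authors' deposited table. Of 17 myofibroblast and smooth muscle markers, 0 rose and 1 fell in the authors' deposited table (1 adjusted over the list alone), Aspn at -0.55 ± 0.13, while Acta2 stood at 0.40 ± 0.39. Of 14 pericyte markers, 0 rose and 1 fell in the authors' deposited table (1 adjusted over the list alone), the transcription factor gene Ebf1 at -0.62 ± 0.19, adjusted p = 0.0459. Adjusted over all genes with a p-value, Plin2 (0.0688) and Ebf1 (0.0665) did not pass. None of the 12 mesothelial markers passed in the authors' deposited table (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). Upk3b, the most abundant of them, stood at -0.47 ± 0.62 in the authors' deposited table, a standard error too wide to exclude a shift. The cameraPR adjusted p of these lists was 0.600, 0.961, 0.932, 0.393 and 0.551 in the order given.

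Elastin rose while fibrillar collagens did not pass. Eln, which encodes the core protein of elastic fibres (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), rose by 0.81 ± 0.20 in the authors' deposited table, adjusted p = 0.00266, and was the 1 of 22 elastic fibre and protease genes to pass (1 adjusted over the list alone). In the authors' deposited table Ltbp2 stood at 1.05 ± 0.39, Mmp14 at 0.31 ± 0.12 and Ltbp4, the most abundant member, at -0.02 ± 0.14. Of 24 collagen and matrix genes, 0 rose and 2 fell in the authors' deposited table: Col12a1 at -0.59 ± 0.10 and Spp1, the gene of osteopontin, at -0.88 ± 0.15. Adjusted over the list alone, 4 were higher, among them Timp1, Sparc and Col4a2, and 3 lower (Cthrc1 in addition). Col1a1 (0.28 ± 0.17) and Col3a1 (0.29 ± 0.17) did not pass in the authors' deposited table. The cameraPR adjusted p was 0.126 for the elastic fibre list and 0.313 for the collagen list. On ranks the collagen list had an adjusted p of 0.0107. Its direction was higher in both forms, with 18 members above 0 and 6 below in the authors' deposited table.

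**Figure D2:**
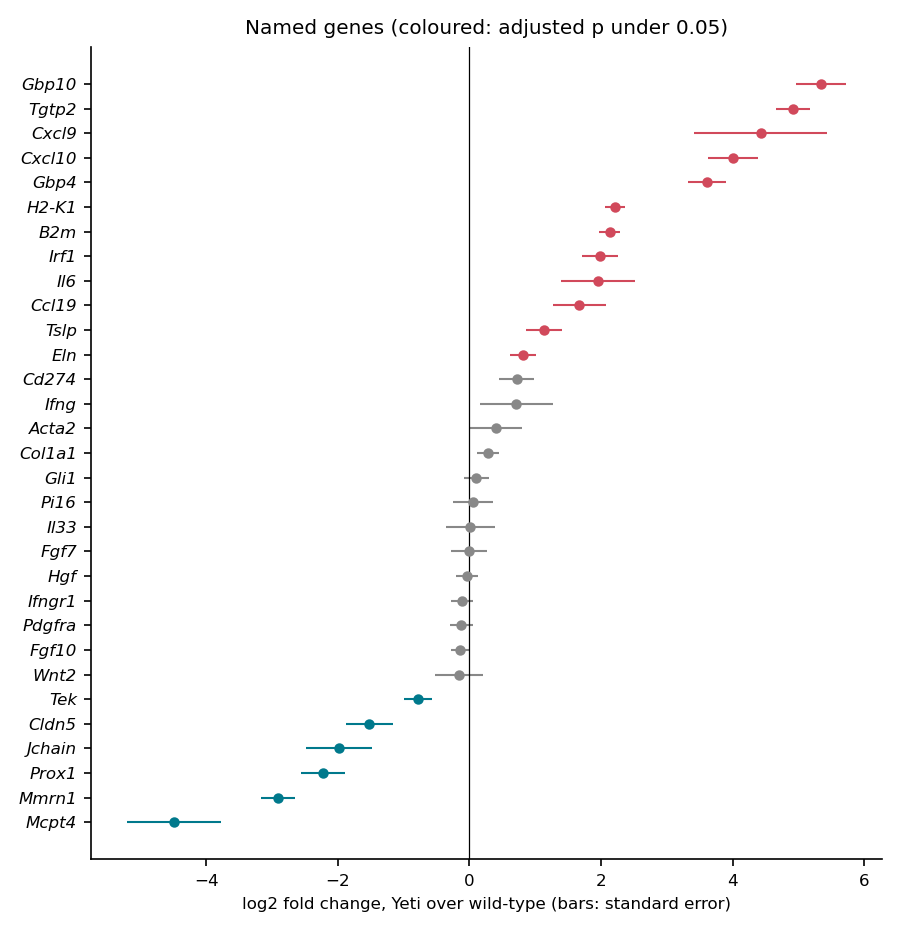
Log2 fold change of Yeti over wild-type for 31 genes in the authors' deposited table, with bars of 1 standard error. Coloured points passed an adjusted p of 0.05: interferon targets and chemokines lie at the top (Gbp10 at 5.34), and endothelial, plasma cell and mast cell genes at the bottom (Mcpt4 at -4.49), while Pdgfra, Fgf10 and Wnt2 lie near 0.

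Secreted factors that act on the lung epithelium changed at 2 of 26 genes. The Wnt antagonist family member Dkk3, the most abundant, rose by 0.41 ± 0.11, and Dkk2 fell by 1.74 ± 0.40 in the authors' deposited table. Adjusted over the list alone, 3 were higher (Dkk3, Sfrp1, Igf1) and 2 lower (Dkk2, Rspo2). The growth factors Fgf7 (fitted levels of 2114 normalized counts in wild-type and 2109 in Yeti) and Hgf (-0.04 ± 0.17) did not pass in the authors' deposited table, and cameraPR gave the list an adjusted p of 0.961. None of the 11 hedgehog pathway genes passed in the authors' deposited table (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). The hedgehog target Gli1 stood at 0.11 ± 0.19 in the authors' deposited table (list adjusted p = 0.743).

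Several response programmes shifted as lists, by cameraPR p-values that rest on the preset inter-gene correlation. Where members of a list vary together between libraries, these p-values may be too small. Of 16 TGF-β and BMP signalling genes, 3 rose and 0 fell in the authors' deposited table (3 adjusted over the list alone): the BMP-induced Id2 (0.74 ± 0.20) and Id3 (0.86 ± 0.26) and the inhibitory Smad7 (0.46 ± 0.14), with a list adjusted p of 0.00668. Adjusted over all genes with a p-value, Smad7 (0.0662) did not pass. Of 14 senescence-associated genes, Ccnd1 (1.38 ± 0.24), Gdf15 (1.23 ± 0.23) and Il6 rose and Trp53inp1 fell (-1.17 ± 0.24) in the authors' deposited table, list adjusted p = 0.00215. Adjusted over the list alone, 5 were higher, Igfbp7 among them, and 1 lower. The cell cycle inhibitor Cdkn1a, at 0.65 ± 0.31, did not pass in the authors' deposited table. Immediate-early genes, which tissue dissociation also induces, were higher as a list (median 0.51, adjusted p = 1.88e-08). In the authors' deposited table, 3 of 24 rose and 0 fell (5 adjusted over the list alone, with Ier2 and Atf3): Btg2 (0.64 ± 0.17), Nr4a1 (1.01 ± 0.30) and Ier3 (0.87 ± 0.27), the last of which did not pass when adjusted over all genes with a p-value (0.0693). Cholesterol synthesis genes were lower as a list (median -0.49, adjusted p = 3.28e-04), with 17 of 18 below 0 in the authors' deposited table. None passed singly in the authors' deposited table (0 adjusted over the list alone, 2 lower at an unadjusted p under 0.05), Msmo1 standing at -0.65 ± 0.34. Of 22 cell cycle genes, 0 passed in the authors' deposited table (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), with Mki67 at -0.64 ± 0.59 and a list adjusted p of 0.295.

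Markers of some cell types outside the mesenchyme moved with genotype. Of 17 endothelial markers, 0 rose and 7 fell in the authors' deposited table (9 lower adjusted over the list alone, with Cdh5 and Ednrb), with a median of -0.78 and a list adjusted p of 5.77e-17. The lymphatic genes Mmrn1 (-2.91 ± 0.26; ENSMUSG00000054641, chromosome 6, 60924976 to 60989378) and Prox1 (-2.22 ± 0.33) and the sialomucin Emcn (-1.98 ± 0.38) fell, while Pecam1, which encodes CD31, stood at 0.25 ± 0.46 in the authors' deposited table. Reln, which lymphatic endothelium expresses (ENSMUSG00000042453, chromosome 5, 21884454 to 22344702), fell by 3.43 ± 0.29 in the authors' deposited table. Of 11 B and plasma cell markers, 0 rose and 3 fell in the authors' deposited table (3 adjusted over the list alone): the antibody joining chain Jchain (-1.98 ± 0.51), Igkc (-1.82 ± 0.53) and Mzb1 (-1.75 ± 0.55), list adjusted p = 6.50e-06. Adjusted over all genes with a p-value, Mzb1 (0.0715) did not pass. Igkc stood at a fitted 76522 normalized counts in wild-type and 21683 in Yeti in the authors' deposited table. Of the 12 genes with the lowest fold changes named by rule, 9 were immunoglobulin variable segments, from Igkv17-127 (-2.87 ± 0.58) to Igkv6-32 (-3.44 ± 0.50) in the authors' deposited table. The lowest of the 12 was Bpifa1, a secreted airway epithelial protein gene (ENSMUSG00000027483, chromosome 2, 154142880 to 154149219), at -4.04 ± 0.71 in the authors' deposited table.

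T and NK markers were lower as a list (median -0.73, adjusted p = 0.00306), although 0 of 18 passed singly in the authors' deposited table (2 lower adjusted over the list alone, Cd4 and Klrb1c). Cd4 stood at -1.59 ± 0.56 and Prf1 at -0.88 ± 0.35 in the authors' deposited table. A list of 12 mature T and NK genes, written after the values were seen, was not lower (median -0.02, 6 above 0 and 6 below). Of the 18 fixed markers, 2 were higher and 5 lower at an unadjusted p under 0.05 in the authors' deposited table. Macrophage and monocyte markers went the other way, with 0 of 19 passing in the authors' deposited table and 3 higher adjusted over the list alone: Fcer1g (1.70 ± 0.56), the colony-stimulating factor receptor gene Csf1r (1.77 ± 0.60) and Ear2 (0.72 ± 0.26). At an unadjusted p under 0.05, 6 were higher and 0 lower, and the pan-leukocyte gene Ptprc, which encodes CD45, stood at 0.16 ± 0.50 in the authors' deposited table. Cd300e (4.73 ± 0.67), Treml4 (4.12 ± 0.64) and Fcgr4 (3.82 ± 0.52), myeloid receptor genes among the 12 with the highest fold changes, rose in the authors' deposited table, as did the lipid phosphodiesterase gene Smpdl3b (3.70 ± 0.65). Of 12 neutrophil and mast cell markers, 1 fell and 0 rose in the authors' deposited table (1 adjusted over the list alone), the mast cell protease gene Mcpt4 at -4.49 ± 0.71. Cpa3 (-0.28 ± 0.34) and Kit (-0.21 ± 0.28) stayed short of the threshold in the authors' deposited table. That list had a median of 0.06 but a mean of -0.20 and a cameraPR direction of lower, adjusted p = 0.452. Of 8 Schwann and neural markers, Cdh19 (-1.57 ± 0.42) fell in the authors' deposited table (4 lower adjusted over the list alone, Sox10 among them), list adjusted p = 0.00877. Of 8 erythroid and platelet markers, the platelet chemokine gene Ppbp rose by 2.52 ± 0.65 in the authors' deposited table (1 adjusted over the list alone), list adjusted p = 0.0255 (0.109 over genes with a mean of at least 1 CPM). Of 20 epithelial markers, 0 passed in the authors' deposited table (0 adjusted over the list alone, 3 lower at an unadjusted p under 0.05), with Scgb1a1 at -0.97 ± 0.38 and a list adjusted p of 0.138.

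**Figure D3:**
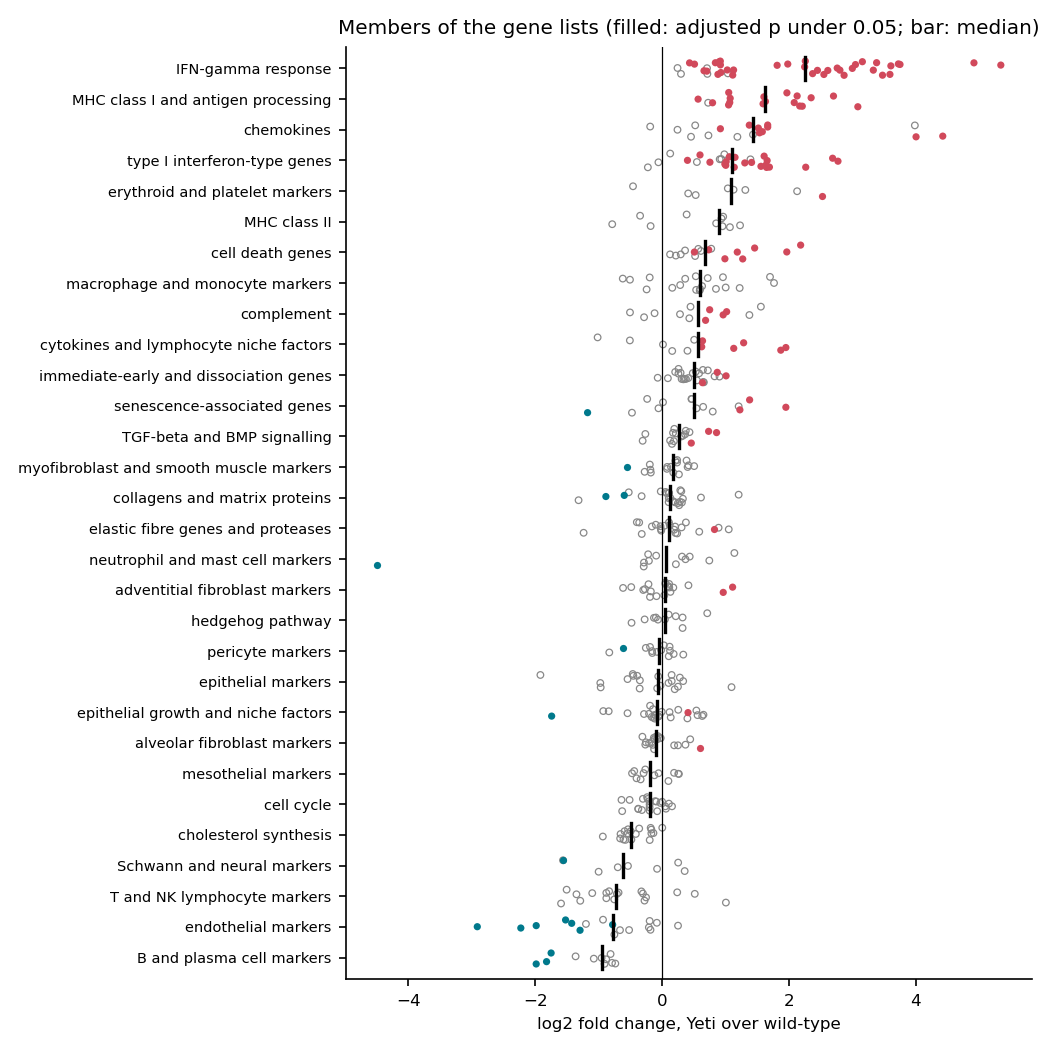
Log2 fold change of Yeti over wild-type (x axis) of each tested member of the 30 tested gene lists in the authors' deposited table, 1 row per list and 1 point per gene, ordered by the list median (bar). Filled points passed an adjusted p of 0.05. The IFN-γ list has the highest median (2.25) and the B and plasma cell list the lowest (-0.95).

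Because the table holds no values per library, single libraries could not be inspected, and the p-values cover only the spread between the 6 libraries, which the labels do not say came from separate animals. The cameraPR p-values of all lists rest on the preset inter-gene correlation and may be too small where members vary together between libraries. Members of the Gbp, Tgtp, H2-Q, Apol9, Ly6 and immunoglobulin families share sequence, so how reads were split among them is uncertain.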

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

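All alternatives reuse the authors' statistics, so they test thresholds and scaling and not the libraries. No paired analysis was possible because the table holds no values per library, and for the same reason leaving out each library, other splits of the 6 libraries, another count test, DESeq2 or voom refits and fry were not run. A fold of at least 2 left 240 genes higher and 174 lower, and an adjusted p of 0.01 left 255 and 117, since fewer genes pass by construction. Adjustment over all genes with a p-value gave 337 and 177. The settings in the rest of this paragraph were chosen after seeing the data. Bonferroni adjustment left 148 genes higher and 52 lower. Without immunoglobulin genes 351 were higher and 128 lower, so they are not most of the lower calls. The counts were 359 and 190 over genes with a mean of at least 1 normalized CPM, 422 and 243 with an empirical null (statistic divided by its robust SD of 0.955) and 359 and 206 after recentring by 0.0055. All 30 lists kept direction and call after recentring, which took Ier3, Plin2 and Smad7 to adjusted p of 0.0507 to 0.0513. With a preset correlation of 0.05, the class II list (adjusted p = 0.0509) and the erythroid and platelet list (0.0514) lost their call, and the latter also over genes with a mean of at least 1 CPM (0.109). On ranks the adventitial list (0.994) and the neutrophil and mast cell list (0.879) turned direction without passing in either form. The collagen list passed on ranks as higher (0.0107). The cause of these changes was not tested. Adjusted over all genes with a p-value, 0 alveolar markers rose and 0 pericyte markers fell, against 1 each, and Ebf1, Ier3, Mzb1, Plin2 and Smad7 no longer passed (adjusted p from 0.0662 to 0.0715). With the empirical null, 1 class II gene, 1 collagen or matrix gene, 2 epithelial niche factors, 5 senescence-associated genes and 1 macrophage marker were higher, against 0, 0, 1, 3 and 0 (H2-DMb1, Sfrp1, Igfbp7 and Fcer1g were among those that passed in addition). In the authors' deposited table an adjusted p exists only from a mean count of 4.57, so genes below it were not called.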

Other observations

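Apart from the fixed lists with their cameraPR tests and the genes named by the report's rule, the tests, lists and genes of this part were chosen after the table had been looked through, including its called genes. Beside Bpifa1, the airway genes Bpifb1 (-2.98 ± 0.77, SE, log2), Muc5b (-2.29 ± 0.62) and Scgb3a1 (-2.65 ± 0.72) fell in the authors' deposited table, picked because they passed. The airway genes Scgb3a2 (-1.92 ± 0.73) and Scgb1a1 (-0.97 ± 0.38) did not pass, nor did any of the 20 fixed epithelial markers in the authors' deposited table (3 lower at an unadjusted p under 0.05). Of 9 measured mast cell genes, 3 fell and 0 rose in the authors' deposited table (median -0.21, 4 above 0): the protease genes Mcpt4 (-4.49 ± 0.71), Tpsb2 (-4.31 ± 0.55) and Cma1 (-3.34 ± 0.54). The others in the authors' deposited table were Cpa3 (-0.28 ± 0.34), Kit (-0.21 ± 0.28), Fcer1a (0.58 ± 0.62), Ms4a2 (0.77 ± 0.68), Hdc (0.84 ± 0.53) and Gata2 (1.01 ± 0.60). Of 13 plasma cell genes, 8 fell in the authors' deposited table (median -1.63), among them Tnfrsf17 at -2.54 ± 0.53 and Igha at -2.25 ± 0.53. Of 217 immunoglobulin genes with an adjusted p, 65 fell and 0 rose in the authors' deposited table (median -1.77; 129 lower and 2 higher at an unadjusted p under 0.05).

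Single genes outside the lists that rose in the authors' deposited table were Il12b (3.67 ± 0.40), Il27 (2.89 ± 0.76), the itaconate enzyme gene Acod1 (2.78 ± 0.61), Icam1 (0.78 ± 0.15) and Vcam1 (0.61 ± 0.18). The fixed macrophage and monocyte list was higher in the same libraries (median 0.60, cameraPR adjusted p = 0.00668), and myeloid cells express several of these genes. No rise was seen across 7 classical monocyte (median -0.01), 8 alveolar macrophage (0.09) or 9 pan-leukocyte genes (-0.02). Of each of these lists 0 genes passed in the authors' deposited table. Of 23 killer cell lectin-like receptor genes, by symbol, 5 fell and 1 rose in the authors' deposited table: Klra8 (-4.15 ± 0.99), Klra4 (-2.88 ± 0.79), Klrb1 (-2.77 ± 0.58), Klrg2 (-2.15 ± 0.55) and Klri2 (-1.92 ± 0.53) fell and Klra2 (2.35 ± 0.44) rose. Klrb1c (-1.10 ± 0.39) and Klrd1 (-0.30 ± 0.43) were among those that did not pass in the authors' deposited table. Around Ifng, 0 of 58 genes with an adjusted p within 5 Mb to each side passed in the authors' deposited table (4 at an unadjusted p under 0.05), and 1 of 134 within 10 Mb did, the interferon signalling gene Stat2 at 1.13 ± 0.15.

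Genes of lymphatic endothelium fell: 6 of 8 measured in the authors' deposited table, among them Reln, Mmrn1, Flt4 (-2.22 ± 0.25), Prox1, Lyve1 (-1.58 ± 0.31) and Tbx1 (-1.38 ± 0.37), on a list written after these 6 had been seen to pass and sharing 2 genes with the fixed endothelial list. The fixed endothelial list already held 2 lymphatic genes, Prox1 and Mmrn1, and 6 blood endothelial genes (median -0.59). Of these 6, 5 lay above Prox1 and 6 above Mmrn1 by more than 2 combined standard errors in the authors' deposited table. That test was set up after the values were known, when a comparison with the picked list (difference of medians -1.52, permutation p = 0.00384) had been set aside. It shows that Prox1 and Mmrn1 fell further than most of these blood endothelial genes. It cannot decide on an equal loss of blood and lymphatic endothelial cells, since its outcome was known when it was written. The cell source of the blood endothelial transcripts was not tested either. The lymphatic genes Sema3d and Foxc2 lay within or above the range of the 6 blood endothelial genes (-0.93 to -0.19). An equal or smaller loss of blood endothelial cells stays open. Of 14 blood endothelial genes, 13 lay below 0 (median -0.38) in the authors' deposited table. Of the same 14, 0 passed and 1 was lower at an unadjusted p under 0.05. Of 16 pan-endothelial genes, which both kinds express, 7 fell in the authors' deposited table (median -0.92). A smaller share of lymphatic endothelial cells, which the CD31 gate should remove, may account for the pattern. The lymphatic median of -1.9 does not settle it, since 6 genes of the list had been seen to pass. Foxc2 stood at 0.33 ± 0.27 and Sema3d at -0.27 ± 0.27 in the authors' deposited table. Sema3d was the most abundant at a mean of 2589 normalized counts, and the next, Mmrn1, had 480. Which cells the Sema3d and Foxc2 transcripts came from was not tested, so these genes do not count against a smaller share either. Altered expression per cell under the Yeti genotype stays open and untested.

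Genes of non-classical monocytes rose: 9 of 16 in the authors' deposited table, median 1.99, all 16 above 0 and 2 of them also in a fixed list. The fixed B and plasma cell list was lower (median -0.951, cameraPR adjusted p = 6.50e-06), as was the fixed T and NK list (median -0.73, adjusted p = 0.00306). Both p-values rest on the preset inter-gene correlation. Markers of the same cell type may vary together between libraries, so these p-values may be too small. All 11 B and plasma cell markers lay below 0, but only 3 passed singly in the authors' deposited table: Jchain, Igkc and Mzb1. More leukocytes of every kind are argued against for these 3 genes only. A comparison with pan-leukocyte genes (difference of medians 2.01, permutation p = 3e-04) was set aside, since 9 of the 16 had been seen to pass. Carry-over of these monocytes past the CD45 gate and interferon-induced expression in the mesenchymal cells could not be separated: 6 lineage genes had a median of 0.873, from Spn at 0.07 ± 0.59 to Csf1r at 1.77 ± 0.60 in the authors' deposited table, but they were kept because they had not passed, which pulls the median down. A first form of this test, with 3 more genes that had been seen to pass, gave a median of 1.35 and favoured carry-over; its list and criterion were changed after that result was seen, and neither form decides. The genotype effect on monocyte numbers stays open and untested.

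Thymocyte genes showed large differences between libraries: of 13 measured, 6 had no p-value in the authors' deposited table, among them Rag1 (-3.23 ± 1.35), Dntt (-3.45 ± 1.51) and Cd8a (-1.89 ± 1.19), and all 13 lay below 0, 5 of them also in a fixed list. Their median lay below that of 12 mature T and NK genes (difference -1.57, permutation p = 0.00012 over genes; 9 of the 12 above it by more than 2 of their standard errors). The mature genes themselves had a median of -0.02, with 6 above 0 and 6 below, so no fall was seen across them. But the thymocyte list was picked for this pattern, 6 of its fold changes come without a p-value, and it holds general T cell genes such as Lck and Cd4. The fixed T and NK list, which also holds Cd4, was lower too (median -0.73, 15 of 18 below 0). More T and NK cells of every kind in wild-type libraries therefore stay open. Thymus cells in part of the wild-type libraries stay open too: the median coefficient of variation of the 7 thymocyte genes with a p-value lay at percentile 99.98 among 10000 lists matched on expression, yet 30 of 43 lists lay above percentile 99, so this measure cannot single them out. That test was first run on all 13 genes, with percentile 100, and then narrowed. Which libraries carry the signal cannot be seen in this table. CD45-positive thymocytes should have been removed by the gate, but leukocyte transcripts were present. Ptprc, which encodes CD45, had a mean of 4871 normalized counts and Igha of 123311 in the authors' deposited table. The gate alone therefore does not weigh against thymus cells.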
